A study of Homo sapiens with 5 samples.

How the data were processed

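Total RNA of 5 samples of SVG-10B1 cells was sequenced on Illumina HiSeq instruments, per the labels' protocols. The submitters' processing notes name Trimmomatic, STAR and HTSeq, which are in general use a read trimmer, an aligner and a read counter, and the genome build hg19 (GRCh37), without versions or roles. The annotation release and the strand setting of the counting are not given in the sources used here. The deposited values are whole-number counts of reads per gene, not normalized, with 1 file per library. Each file listed 63677 Ensembl genes with symbols. Of these, 5772 had an empty value in the files and were treated as not measured, which left 57905 genes with counts, and 0 entries named no gene. A symbol stood for more than 1 gene identifier in 244 cases, and genes were therefore matched by identifier.

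Samples were grouped by genotype and clone number as the labels give them, with 2 wild-type libraries, 1 of clone 2 and 2 of clone 6. The labels give the wild-type line the clone number 1. Counts were analysed in R 4.3.3 with edgeR 4.0.16, using TMM scaling, the default filterByExpr filter, which kept 16471 genes, and the quasi-likelihood F test. The genotype fit had 3 residual degrees of freedom, and the fit with 3 groups, used for each clone and for the difference between clones, had 2. Genes were called at a Benjamini-Hochberg adjusted p below 0.05. CPM were computed on library sizes scaled by TMM. On unscaled totals 3 reads were 0.137 to 0.221 CPM, and on the scaled library sizes, used for the floor of genes at 0, 0.1385 to 0.2295 CPM. The log2 CPM used a prior count of 2. Gene lists were tested with camera from limma 3.58.1 with an inter-gene correlation of 0.01, two-sided, over the 39 of 41 lists with at least 5 tested members. Camera was repeated with an estimated correlation, under which 0 of the 15 called lists kept their call (lowest adjusted p = 0.668). This version takes its p-values from the residual degrees of freedom, 3 for the genotype, so few lists can pass it. Estimated correlations of the neuron (-0.055), HOX (-0.022) and TGF-beta lists (-0.005) were below 0.01, and each had an adjusted p of 0.668. A lost call there does not by itself show correlation between genes. In contrast, the ribosomal protein (0.869), cholesterol (0.635) and inflammatory lists (0.615) had estimated correlations far above 0.01. Camera p-values at 0.01 can be too low for such lists. Fry called 12 lists in 1 direction and 36 in either direction. The 12 held 9 of the 15 lists called by camera. The other 6 were the ribosomal protein (fry adjusted p = 0.19), NADPH (0.19), glutamate (0.247), cholesterol (0.327), protocadherin (0.194) and interferon lists (0.0705). The remaining 3 called by fry and not by camera were the Hippo component (0.0192), oligodendrocyte (0.0245) and IDH-mutant glioma lists (0.00676). Fry asks whether the genes of a list move on balance 1 way and does not compare them with other genes. The gene lists, the tests, the rule for named genes and most alternatives were set before the data were examined.

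Named genes were IDH1, YAP1, WWTR1 and the NOTCH receptors, the 12 largest rises and 12 largest falls with an average log2 CPM of at least 2 and all edited libraries on the same side of both wild-type libraries, up to 5 each way per clone comparison, and up to 4 called members per list. The rule was met by 1002 rises and 1148 falls. Some genes that meet the rule are not reported here. Where a group had 0 reads, the fold is a lower bound against a floor of 3 reads per library. Where it had 1 to 3 reads, an exact 95% interval of the ratio is given. Intervals and floors cover counting error only. Overlap between the clone comparisons was set against 20 simulations of unchanged clones. Segments of chromosomes used gene start positions, chromosome and GC content from GENCODE 29, a GRCh38 annotation, joined by gene identifier. The positions gave the gene order, and the widest gap between annotated genes parted the arms, except for chromosomes taken as a long arm only.

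The procedure was tested on simulated data with 200 changed genes, drawn from the wild-type means and the library sizes of the real samples. Every library was drawn independently, although the real clone 2 and clone 6 replicate 1 libraries were nearly identical, so the shares below leave this out. With a spread estimated per gene, the genotype comparison (15734 genes tested) recovered 16.4, 77.6 and 98.5% of genes changed 1.5, 2 and 4-fold, and 19 of 147 calls (12.9%) were unchanged genes, above the nominal 5%. Clone 6 against wild type (15737 genes) recovered 6, 55.2 and 100% with 24 of 131 calls (18.3%) unchanged, and clone 2 against wild type (15735 genes) 6, 40.3 and 95.5% with 26 of 120 calls (21.7%) unchanged. A simulation with a spread that follows the trend with expression was added after these results were seen. There the share of unchanged genes among calls was 2.8% for the genotype (22.4, 86.6 and 100% recovered over 15681 genes), 3.8% for clone 6 (10.4, 82.1 and 100% over 15680 genes) and 0% for clone 2 (6, 26.9 and 98.5% over 15681 genes). Calls can therefore hold more unchanged genes than the adjusted p states where genes differ much in their spread. In a simulated test of camera, 1 list of 25 genes raised 1.7-fold was called and 0 of 38 unchanged lists. Its genes were drawn independently, so it does not show how camera behaves on lists of correlated genes.

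Alternatives covered the scaling, the low-count filter, DESeq2 1.42.0, limma-voom, a replicate block, a fit with 3 groups, a minimum fold and each library left out. Summing the clone 2 and clone 6 replicate 1 libraries, leaving out ribosomal RNA genes, using their share as a covariate, leaving clone 6 libraries out of the list test between clones, estimating the correlation with 1 library left out and giving each clone its own wild-type library were added after the data were seen. Gene counts hold no allele information, so the edit was not analysed here.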

Results

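Gene expression was measured by RNA sequencing of total RNA in SVG-10B1, an established human astroglial cell line, and in derivatives that carry the R132H substitution in 1 of the alleles of IDH1, written R132H/WT. IDH1 encodes the cytosolic isocitrate dehydrogenase, and the substituted enzyme makes 2-hydroxyglutarate, an inhibitor of dioxygenases that use 2-oxoglutarate. The series held 2 wild-type libraries, 1 library of an edited clone numbered 2 and 2 libraries of an edited clone numbered 6. Reads assigned to genes came to 21881726 and 17603317 in wild-type replicates 1 and 2, 14802585 in clone 2, and 13572114 and 16559077 in clone 6 replicates 1 and 2. Ribosomal RNA genes took 7.23, 2.24, 0.42, 9.79 and 0.63% of these reads, in the same order. The labels do not say whether replicates are separate cultures, so the p-values measure the spread between these samples, which may be technical. Adjusted p-values of genes are Benjamini-Hochberg values from edgeR's quasi-likelihood test.

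IDH1 itself (ENSG00000138413, chromosome 2) had similar transcript levels in every library, with 119 and 117 CPM in wild-type replicates 1 and 2, 110 CPM in clone 2, and 104 and 109 CPM in clone 6 replicates 1 and 2. The mean was 118 ± 1.33 CPM in wild type (SD, n = 2) and 108 ± 3.17 CPM in the clones (SD, n = 3), a log2 fold change of -0.13 (SE 0.083, adjusted p = 0.313). Gene counts carry no base calls, so they do not show the edit itself. The clone 2 library and the library labelled clone 6 replicate 1 lay closer together than either labelled replicate pair, with a coefficient of variation of 2.68% against 9.64% for the wild-type pair and 22.2% for the clone 6 pair. Their counts still differed by more than sampling noise, with a median chi-square 1.43 times the expected value and 1.35% of 14557 genes at an unadjusted p below 0.001, where 0.1% is expected.

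**Figure D1:**
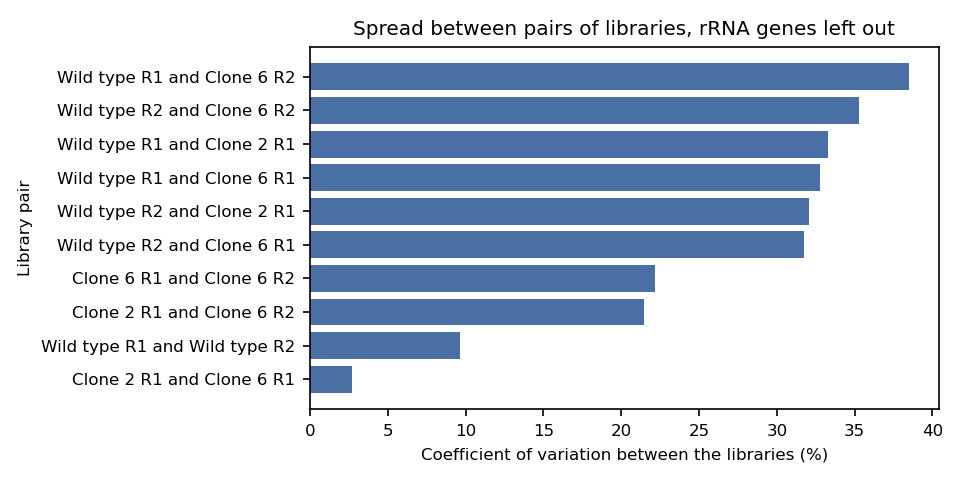
Bars give the coefficient of variation between each pair of libraries in percent, beyond counting noise and with ribosomal RNA genes left out. The pair of clone 2 and clone 6 replicate 1 has the shortest bar (2.68%), followed by the wild-type pair (9.64%).

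The comparison of the 3 edited libraries with the 2 wild-type libraries asked which transcripts differ between the edited clones and the wild-type line. Without further unedited clones, differences tied to the IDH1 edit and to the clones themselves cannot be told apart. In this comparison n counts libraries, not independently edited clones. Several transcripts of the wild-type line were absent or nearly absent in every edited library. EPB41L3, a linker of membrane proteins to the cytoskeleton, fell from 35.4 ± 10.1 CPM (SD, n = 2) to 0 reads in all 3 edited libraries (at least 154-fold lower, adjusted p = 0.000656). The BMP antagonist CHRDL1 and the monocyte chemokine CCL2 also fell to 0 reads, at least 116-fold and 74.3-fold lower (adjusted p = 0.000377 and 0.000395). TNC, the matrix glycoprotein tenascin C, fell from 218 ± 7.84 CPM to 0.80 ± 0.0985 CPM (SD, n = 3), a log2 fold change of -8.07 (SE 0.129, adjusted p = 2.01e-06). The other large falls were those of CSF3, PDE1C, HCLS1, ARMCX2, IL7R, TGM2, ABCC9 and CXCL6, with adjusted p-values between 0.000156 and 0.000399. CSF3, a granulocyte growth factor, went from 46.5 CPM (62.6 and 30.4 CPM in wild-type replicates 1 and 2) to 1 read in clone 2, 0 in clone 6 replicate 1 and 4 in clone 6 replicate 2, and PDE1C, a calmodulin-dependent phosphodiesterase, from 49.7 to 0.156 CPM. With 2 and 3 reads left in the edited libraries, HCLS1 and TGM2 had ratios of 273 (95% counting interval 75.2 to 2261) and 147 (50.04 to 717).

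Fewer genes rose than fell. SLC6A5, the neuronal glycine transporter, had 0 reads in both wild-type libraries and rose to 11.7 ± 0.519 CPM (SD, n = 3) in the edited libraries, at least 71.1-fold higher (adjusted p = 0.000258). RAB3C, a GTPase of secretory vesicles, went from 1 read in wild type to 313 reads (ratio 280, 95% counting interval 49.8 to 11080). SLAMF7, an immune cell receptor, rose from 4.20 ± 0.587 to 40.3 ± 3.87 CPM (log2 fold change 3.27, SE 0.164, adjusted p = 0.000249). The Rab regulator TBC1D30 rose by 3.32 on the log2 scale, the mast cell protease CPA3 by 3.23, the anion channel subunit LRRC8B by 3.17 and FRMPD3 by 3.16. RGS5, a regulator of G protein signalling, rose by 3.06, the neurofilament protein INA by 3.05, and ATRNL1 and GAREM by 2.88 each. Without wild-type replicate 2 the log2 fold changes of FRMPD3 and INA were 3.78 and 3.81. FRMPD3 lost its call without wild-type replicate 1 (adjusted p = 0.0763), as did RGS5 without wild-type replicate 1 (adjusted p = 0.0807) or 2 (adjusted p = 0.0782).

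**Figure D2:**
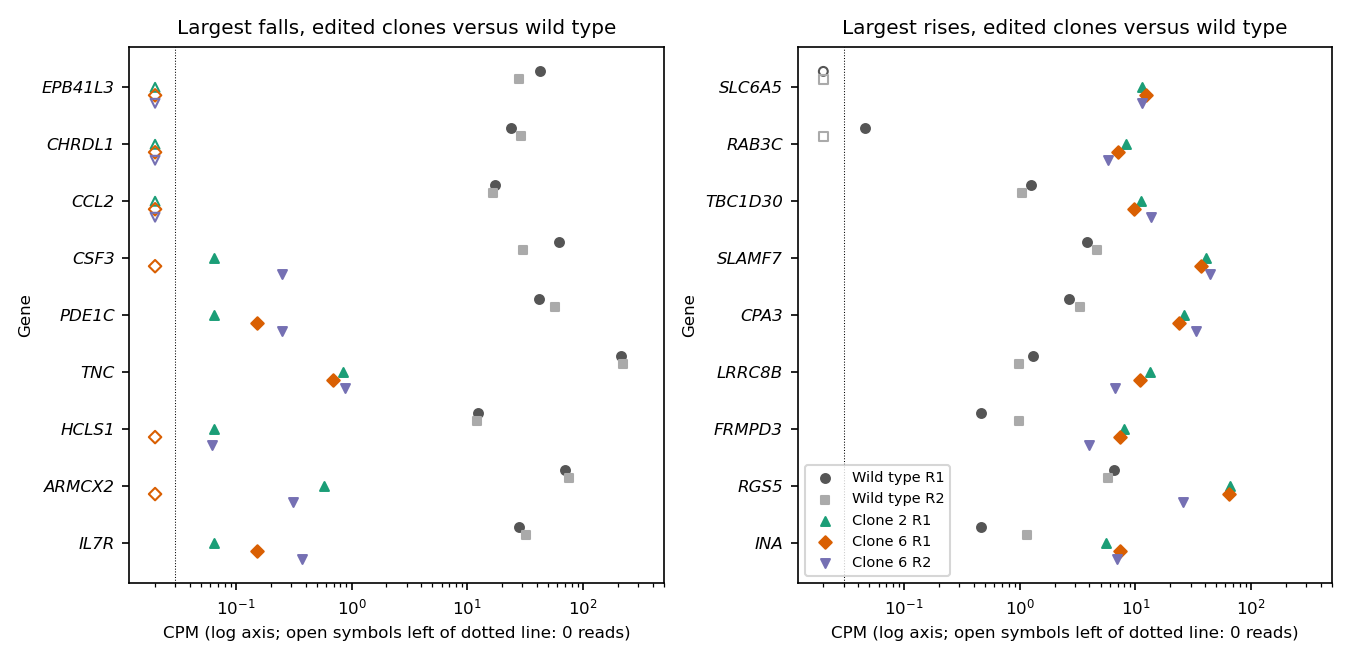
CPM of the 9 genes with the largest falls and the 9 with the largest rises, on a log axis with 1 symbol per library and open symbols for 0 reads. EPB41L3, CHRDL1 and CCL2 have 0 reads in all 3 edited libraries, and SLC6A5 has 0 reads in both wild-type libraries.

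Across the 16471 genes tested, 2822 were called at an adjusted p below 0.05, of which 1259 were higher and 1563 lower in the edited libraries. Changes of at least 2-fold were seen for 471 of the higher and 735 of the lower genes. The values of the genotypes did not overlap for 51.5% of genes, where chance gives 20% if all 5 libraries are independent. The clone 2 and clone 6 replicate 1 libraries were nearly identical, so the share by chance is higher here. The count was 500 without wild-type replicate 1, 697 without wild-type replicate 2, 1481 without clone 2, 1525 without clone 6 replicate 1 and 5971 without clone 6 replicate 2. The last of these fits held only the nearly identical clone 2 and clone 6 replicate 1 libraries as edited samples, which narrows its spread. With these libraries summed into 1, which was chosen after the data were seen, the count was 1528. With the ribosomal RNA share as a covariate, also chosen then, it was 1162.

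Inflammatory genes had the lowest camera p among the 39 lists tested, of 41 fixed before the data were examined. Of 22 tested cytokine and NF-kB target genes, 18 fell and 0 rose (18 and 0 when adjusted over the list alone), with a median log2 fold change of -2.51 (camera adjusted p = 9.64e-11). The correlation between genes of this list was estimated at 0.615, far above the 0.01 set for camera, so this p can be too low. With an estimated correlation between genes the adjusted p of this list was 0.671. That version of camera has few degrees of freedom here, so few lists can pass it, whatever the correlation between genes. Besides CCL2, the neutrophil chemokine CXCL1 fell from 168 to 2.31 CPM (log2 fold change -6.13, SE 0.691, adjusted p = 0.00261) and the cytokine IL32 fell by 5.01 on the log2 scale. CXCL1 had 0.709 CPM in clone 2, 0.612 CPM in clone 6 replicate 1 and 5.62 CPM in clone 6 replicate 2, without which its log2 fold change was -7.98. The shift differed in size between libraries, with list medians of -3.33 in clone 2, -3.45 in clone 6 replicate 1 and -1.76 in clone 6 replicate 2. Of 17 genes of class I antigen presentation, 11 fell and 0 rose (12 and 0 when adjusted over the list alone; camera adjusted p = 1.17e-05, and adjusted p = 0.668 with an estimated correlation). HLA-F fell by 2.79, the immunoproteasome subunit PSMB9 by 1.71 and HLA-B by 1.69 on the log2 scale. The HLA genes are near-identical in parts, so the division of reads among them is uncertain. Of 26 interferon response genes, 7 fell and 1 rose (10 and 2 when adjusted over the list alone; camera adjusted p = 0.0223, and adjusted p = 0.791 with an estimated correlation). BST2, a membrane tether of budding viruses, fell by 2.32 on the log2 scale, but its adjusted p was 0.147 without wild-type replicate 1, 0.126 without wild-type replicate 2, 0.0573 without clone 2 and 0.0678 without clone 6 replicate 1. The antiviral membrane protein IFITM2 fell by 1.87. The interferon list lost its call without clone 6 replicate 2 (adjusted p = 0.0954) and with a filter of 1 CPM (adjusted p = 0.0598).

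Of 26 collagen and matrix genes, 14 fell and 2 rose (16 and 2 when adjusted over the list alone), with a median log2 fold change of -0.92 (camera adjusted p = 5.05e-05, and adjusted p = 0.668 with an estimated correlation). Besides TNC, the laminin chain LAMA4 fell from 38.3 to 0.505 CPM (log2 fold change -6.20, SE 0.311, adjusted p = 0.000249). The collagen COL11A1 rose by 1.94 on the log2 scale, with adjusted p-values of 0.173 and 0.265 without wild-type replicates 1 and 2, 0.110 without clone 2 and 0.110 without clone 6 replicate 1. Of 26 migration and mesenchymal genes, 10 fell and 0 rose (11 and 0 when adjusted over the list alone; camera adjusted p = 0.00127, and adjusted p = 0.671 with an estimated correlation). Migration list medians were -0.48 in clone 2, -0.51 in clone 6 replicate 1 and -0.15 in clone 6 replicate 2. Of 22 TGF-beta targets, 9 fell and 1 rose (10 and 1 when adjusted over the list alone; camera adjusted p = 0.0111, and adjusted p = 0.668 with an estimated correlation). TGF-beta target medians were -0.33 in clone 2, -0.21 in clone 6 replicate 1 and -0.62 in clone 6 replicate 2, and without that library the adjusted p of the list was 0.0640. The smooth muscle protein TAGLN and the matrix protein TGFBI fell by 1.92 and 1.43 on the log2 scale.

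Of 14 HOX genes, 5 fell and 1 rose (6 and 1 when adjusted over the list alone; camera adjusted p = 0.0221, and adjusted p = 0.668 with an estimated correlation). HOXC11 had 1 read left in the edited libraries, a ratio of 43.6 (95% counting interval 7.38 to 1767, adjusted p = 0.0132, and 0.0608 with the ribosomal RNA covariate), and HOXC10 fell by 4.02 on the log2 scale (-4.67 without clone 2 and -3.44 without clone 6 replicate 2). HOXC10 lost its call without wild-type replicate 1 (adjusted p = 0.0872) or 2 (adjusted p = 0.0560), and the HOX list without wild-type replicate 1 (adjusted p = 0.141). Of 25 clustered protocadherins, which are adhesion proteins of neurons, 5 fell and 0 rose (5 and 0 when adjusted over the list alone; camera adjusted p = 0.0219, and adjusted p = 0.824 with an estimated correlation). Protocadherin medians were -0.13 in clone 2 and -0.14 in clone 6 replicate 1, against 0.15 and -0.15 in the wild-type replicates, and -0.67 in clone 6 replicate 2. The protocadherin list lost its call without wild-type replicate 1 (adjusted p = 0.141) or clone 6 replicate 2 (adjusted p = 0.211). Overlapping transcripts and shared sequence make counts in the HOX and protocadherin clusters uncertain, because the strand setting of the counting is not given in the sources used here.

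Among lists that shifted upward, 5 of 34 ribosomal protein genes rose and 1 fell (5 and 1 when adjusted over the list alone; camera adjusted p = 0.0019, and adjusted p = 0.824 with an estimated correlation). RPL5 rose by 0.78 on the log2 scale, with an adjusted p of 0.0640 without wild-type replicate 1 and 0.0503 without wild-type replicate 2. Ribosomal protein medians were 0.17 in clone 2, 0.12 in clone 6 replicate 1 and 0.33 in clone 6 replicate 2. Of 28 genes of NADPH and glutathione metabolism, 3 rose and 2 fell (7 and 2 when adjusted over the list alone; camera adjusted p = 0.0223, and adjusted p = 0.824 with an estimated correlation). The mitochondrial superoxide dismutase SOD2, which is also an NF-kB target, fell by 2.34 on the log2 scale. PGD, a dehydrogenase of the pentose phosphate pathway, rose by 0.95 (adjusted p = 0.0531 without wild-type replicate 1). Of 21 genes of glutamate and branched-chain amino acid metabolism, 4 rose and 1 fell (4 and 1 when adjusted over the list alone; camera adjusted p = 0.026, and adjusted p = 0.824 with an estimated correlation). PRODH, which degrades proline, rose by 1.59 on the log2 scale, with adjusted p-values of 0.178 and 0.165 without wild-type replicates 1 and 2, 0.0785 without clone 2 and 0.0750 without clone 6 replicate 1, and the glutamine synthetase gene GLUL fell by 1.05. Of 24 cholesterol synthesis genes, 3 rose and 1 fell (4 and 1 when adjusted over the list alone; camera adjusted p = 0.0449, and adjusted p = 0.824 with an estimated correlation). Cholesterol list medians were 0.44 in clone 2, 0.43 in clone 6 replicate 1 and -0.04 in clone 6 replicate 2. MSMO1, a sterol oxidase, rose by 1.19 on the log2 scale (adjusted p = 0.0088, but 0.111 without wild-type replicate 1 and 0.0826 without wild-type replicate 2). NADPH list medians were 0.18 in clone 2, 0.17 in clone 6 replicate 1 and 0.39 in clone 6 replicate 2, and those of the glutamate list 0.18, 0.17 and 0.58 in the same order. The NADPH list lost its call without wild-type replicate 1 (adjusted p = 0.141) or clone 6 replicate 2 (adjusted p = 0.137), and the glutamate list did so without the same libraries (adjusted p = 0.141 and 0.160). Cholesterol synthesis lost its call without wild-type replicate 1 (adjusted p = 0.118), wild-type replicate 2 (adjusted p = 0.0796), clone 2 (adjusted p = 0.137) or clone 6 replicate 1 (adjusted p = 0.128), and with upper-quartile scaling (adjusted p = 0.0570) or a filter of 1 CPM (adjusted p = 0.0598).

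**Figure D3:**
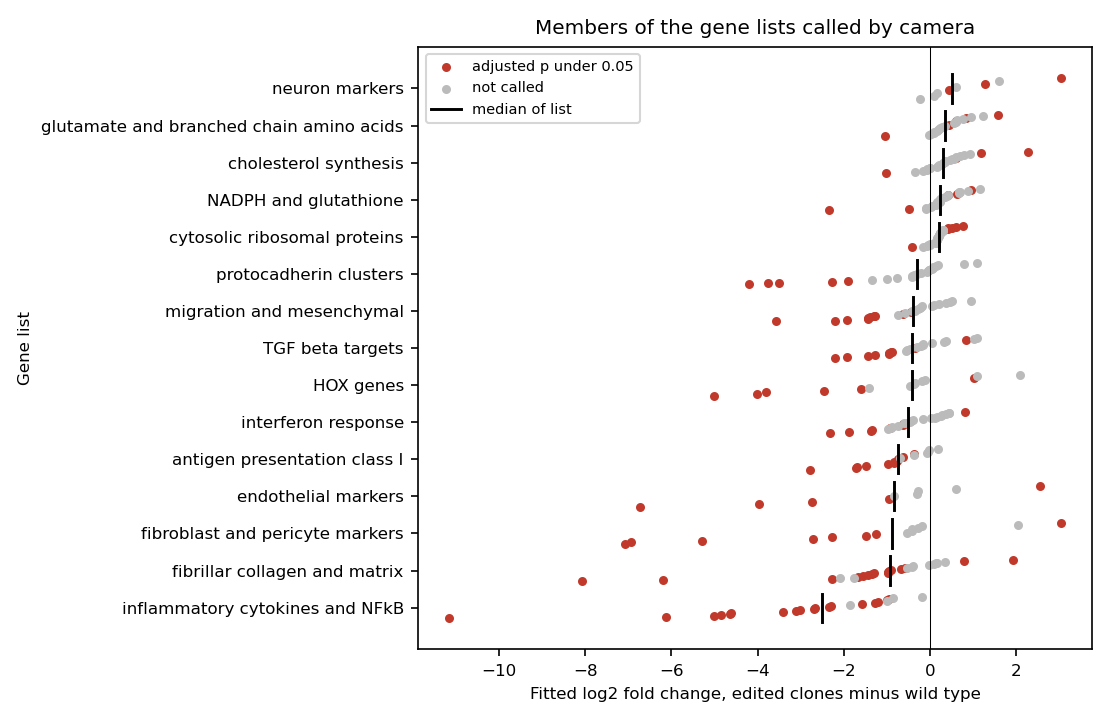
Each point is the fitted log2 fold change of 1 gene, edited clones minus wild type, in the 15 gene lists called by camera, with called genes in red and the list median as a black bar. The inflammatory list has the lowest median (-2.51), and 10 of the 15 lists were shifted downward.

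Markers of other cell types moved in several directions. Of 8 neuron markers, 3 rose and 0 fell (3 and 0 when adjusted over the list alone; camera adjusted p = 0.0223, and adjusted p = 0.668 with an estimated correlation), among them INA and the GABA-synthesising enzyme GAD1 (log2 fold change 1.28, SE 0.151). Neuron list medians were 0.45 in clone 2, 0.27 in clone 6 replicate 1 and 0.80 in clone 6 replicate 2. The neuron list lost its call without clone 2 (adjusted p = 0.0542) or clone 6 replicate 2 (adjusted p = 0.0534). Of 14 fibroblast and pericyte markers, 7 fell and 1 rose (7 and 2 when adjusted over the list alone; camera adjusted p = 0.00127, and adjusted p = 0.671 with an estimated correlation). Medians of these markers were -0.75 in clone 2, -0.72 in clone 6 replicate 1 and -1.91 in clone 6 replicate 2. The potassium channel genes ABCC9 and KCNJ8 fell by 6.94 and 5.28 on the log2 scale, while RGS5 rose (adjusted p = 0.0807 without wild-type replicate 1 and 0.0782 without wild-type replicate 2). Of 9 endothelial markers, 4 fell and 1 rose (4 and 1 when adjusted over the list alone; camera adjusted p = 0.0223, and adjusted p = 0.679 with an estimated correlation), and without wild-type replicate 1 that list had an adjusted p of 0.148. Endothelial medians were -0.77 in clone 2, -0.73 in clone 6 replicate 1 and -1.36 in clone 6 replicate 2. The receptor FLT1 fell to 0 reads, at least 3.33-fold lower (adjusted p = 0.101 without wild-type replicate 2), and the receptor TIE1 fell by 3.97 on the log2 scale, while the transcription factor ERG rose by 2.56 (adjusted p = 0.0563 without wild-type replicate 1 and 0.0827 without wild-type replicate 2). Of 12 astrocyte markers, 2 rose and 3 fell (2 and 3 when adjusted over the list alone; camera adjusted p = 0.472). The gap junction gene GJA1 rose from 162 ± 8.37 to 388 ± 54.6 CPM and CLU from 35.9 ± 2.89 to 115 ± 19.98 CPM (adjusted p = 0.0022 and 0.00177). Besides GLUL, the transcription factor NFIA fell by 2.77 on the log2 scale (adjusted p = 0.00309), and ID4 went from 21 reads to 1 read, a ratio of 23.5 (95% counting interval 3.78 to 972, adjusted p = 0.0273). ID4 lost its call without wild-type replicate 2 (adjusted p = 0.0946) or clone 6 replicate 1 (adjusted p = 0.0814), and without wild-type replicate 1 or clone 2 it did not pass the low-count filter. Neural stem cell (adjusted p = 0.138), oligodendrocyte (adjusted p = 0.830) and epithelial markers (adjusted p = 0.643) were not called by camera, and microglial and immune markers had 2 members and were not tested. For the oligodendrocyte list, which fry called upward (adjusted p = 0.0245), the median was -0.18 and the mean 0.23, and for the epithelial list 0.03 and -0.35.

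Of 22 Hippo pathway components, 2 rose and 3 fell (2 and 3 when adjusted over the list alone; camera adjusted p = 0.551, and fry adjusted p = 0.0192, downward). YAP1 (ENSG00000137693, chromosome 11), the transcriptional coactivator restrained by this pathway, fell from 128 ± 11.1 to 61.3 ± 9.70 CPM (log2 fold change -1.06, SE 0.141, adjusted p = 0.00462). Expression along the long arm of chromosome 11, where YAP1 lies, had a median log2 fold change of -0.47 over 361 expressed genes. YAP1 lost its call without wild-type replicate 1 (log2 fold change -0.97, adjusted p = 0.0650). AMOT, an angiomotin that binds YAP1, fell by 5.63 on the log2 scale (adjusted p = 0.000295), and the pathway scaffold SAV1 rose by 0.63 (adjusted p = 0.171 without wild-type replicate 1 and 0.0876 without wild-type replicate 2). The YAP1 paralog WWTR1 had a log2 fold change of 0.41 (SE 0.189, adjusted p = 0.182), and 0.56 without clone 6 replicate 2 (adjusted p = 0.00124). The edited samples of the latter fit were the nearly identical clone 2 and clone 6 replicate 1 libraries, so its p may be too low. Of 22 targets of YAP and TEAD proteins, 4 rose and 1 fell (5 and 3 when adjusted over the list alone; camera adjusted p = 0.322). The target ANKRD1 rose by 2.18 (SE 0.47, adjusted p = 0.0234, and 0.147 without wild-type replicate 1), and by 2.96 without wild-type replicate 2. CTGF and CYR61, named here after their values were seen, had log2 fold changes of 1.11 and 1.27 (adjusted p = 0.117 and 0.107).

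**Figure D4:**
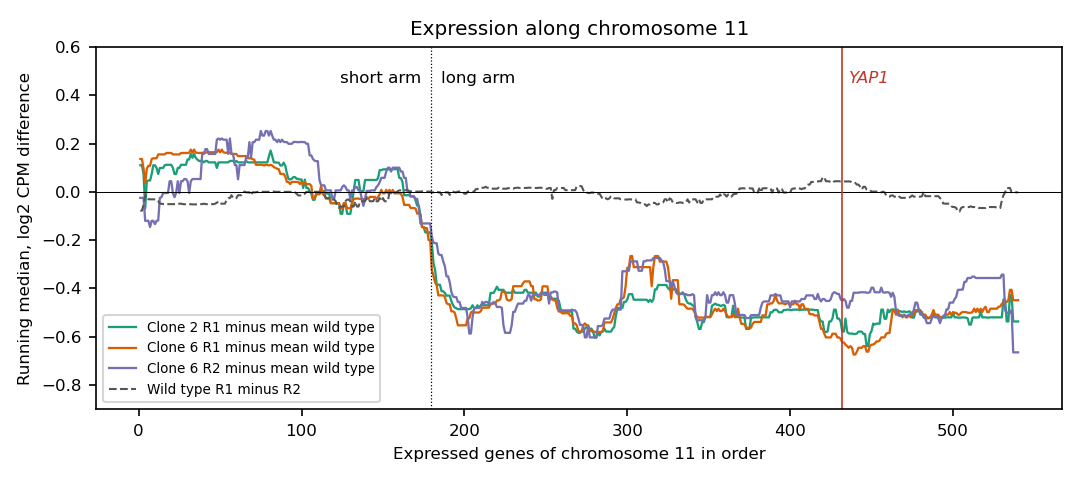
Running median over 41 expressed genes of the difference in log2 CPM along chromosome 11, for each edited library against the wild-type mean and, dashed, between the wild-type replicates. The edited libraries run lower along the long arm (median log2 fold change -0.47) than along the short arm (0.07), and the red line marks YAP1.

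Of 24 tested Notch pathway genes, 3 rose and 6 fell (3 and 6 when adjusted over the list alone; camera adjusted p = 0.477). The receptors had log2 fold changes of -0.07 for NOTCH1 (adjusted p = 0.700), 0.17 for NOTCH2 (adjusted p = 0.235), -0.26 for NOTCH3 (adjusted p = 0.782, and 0.58 without wild-type replicate 1, where the adjusted p was 0.687) and -0.29 for NOTCH4 (adjusted p = 0.558), and none passed the test. The Notch target HEYL was 9.22-fold lower (adjusted p = 0.00564, but 0.0618 without wild-type replicate 1 and 0.0612 without wild-type replicate 2). Among genes tied to the product of the substituted enzyme, 2 of 41 dioxygenases rose and 5 fell (2 and 6 when adjusted over the list alone; camera adjusted p = 0.252, and 0.0478 without wild-type replicate 2, where the adjusted p was 0.719 with an estimated correlation). The collagen hydroxylases LEPREL1 and P4HA2 changed by 1.78 and -1.77 on the log2 scale (adjusted p = 0.000249 and 0.0017). Of 22 genes of DNA methylation and polycomb repression, 1 rose and 3 fell (1 and 3 when adjusted over the list alone; camera adjusted p = 0.615). The methyltransferase DNMT3A fell from 47.0 ± 3.48 to 23.6 ± 0.467 CPM (log2 fold change -0.99, adjusted p = 0.0021). Of 17 genes low or methylated in IDH-mutant glioma, 4 fell and 0 rose (4 and 0 when adjusted over the list alone; camera adjusted p = 0.152, and fry adjusted p = 0.00676, downward), with PDPN, the glycoprotein podoplanin, lower by 12.4-fold (adjusted p = 0.000157).

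No call by camera was reached for the remaining lists fixed in advance. Adjusted p-values were 0.494 for the TCA cycle (2 of 27 genes higher, 4 lower), 0.615 for glycolysis (3 of 24 higher, 1 lower), 0.105 for hypoxia targets (1 of 25 higher, 4 lower) and 0.673 for fatty acid synthesis (1 of 16 higher, 4 lower). They were 0.550 for G1/S genes (4 of 30 higher, 2 lower), 0.494 for G2/M genes (1 of 30 higher, 1 lower), 0.830 for p53 targets (3 of 26 higher, 1 lower) and 0.152 for homologous recombination (0 of 27 higher, 5 lower). They were 0.0999 for ATF4 and unfolded protein response genes (2 of 25 higher, 0 lower), 0.551 for WNT genes (0 of 19 higher, 3 lower) and 0.615 for imprinted genes (3 of 19 higher, 2 lower). For mitochondrially encoded genes the adjusted p was 0.356 (0 of 15 higher, 0 lower), for histones 0.0541 (0 of 19 higher, 1 lower) and for nuclear noncoding RNAs 0.502 (1 of 11 higher, 0 lower). The ATF4 list was called without clone 2 (adjusted p = 0.00801) or clone 6 replicate 1 (adjusted p = 0.00877), with list medians of -0.05 in clone 2, -0.14 in clone 6 replicate 1 and 1.71 in clone 6 replicate 2. Hypoxia targets were called lower without wild-type replicate 2 (adjusted p = 7.15e-06) and leaned upward without wild-type replicate 1 (adjusted p = 0.793), with list medians of 0.35 and -0.35 in wild-type replicates 1 and 2, -0.30 in clone 2, and -0.35 and -0.33 in clone 6. Called lower too were homologous recombination genes without clone 6 replicate 2 (adjusted p = 0.0309) and histones without wild-type replicate 2 (adjusted p = 0.0187), clone 2 (adjusted p = 0.0130) or clone 6 replicate 1 (adjusted p = 0.0336). With the same libraries left out and an estimated correlation, a test added after the data were seen, 0 of these calls held, with adjusted p-values of 0.793 and 0.857 for ATF4, 0.666 for hypoxia, 0.579 for homologous recombination, and 0.798, 0.793 and 0.857 for histones. Without clone 6 replicate 2, as for homologous recombination, the edited samples were only the nearly identical clone 2 and clone 6 replicate 1 libraries. The glycolysis list had a median of 0.09 and a mean of -0.09, and the WNT list a median of -0.09 and a mean of 0.02. Cancer-testis genes had 3 tested members and no list test, and PAGE1 rose from 0 reads, at least 12.1-fold, but lost its call without wild-type replicate 1 (adjusted p = 0.0547).

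Clone 6 was set against wild type to show which changes its libraries carry. Its replicate 1 was nearly identical to the clone 2 library (coefficient of variation 2.68%, against 22.2% for the clone 6 pair). The comparison therefore cannot show which changes clone 6 carries apart from clone 2. The 5 largest rises and 5 largest falls of clone 6 were all among the genes named for the genotype comparison. EPB41L3, CHRDL1 and CCL2 had 0 reads in both clone 6 libraries, and SLC6A5 had 11.9 CPM in clone 6 (adjusted p = 0.00123). TNC had a mean of 0.781 CPM against 218 CPM in wild type (log2 fold change -8.10, SE 0.195, adjusted p = 5.28e-05), and YAP1 a mean of 64.2 CPM (log2 fold change -0.99, SE 0.165, adjusted p = 0.0185). In this comparison 1479 genes were called, 637 higher and 842 lower. The count was 329 without wild-type replicate 1, 401 without wild-type replicate 2, 5119 without clone 6 replicate 1 and 3455 without clone 6 replicate 2. With 1 library left out, these p-values took their spread from the remaining pair of replicates alone, clone 6 or wild type, and likewise for clone 2 and the shared calls.

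Clone 2 had 1 library, which was assumed to vary like the others. EPB41L3, CHRDL1, CCL2 and TGM2 had 0 reads in it, SLC6A5 had 11.4 CPM (adjusted p = 0.00501) and TNC 0.838 CPM (log2 fold change -8.01, SE 0.265, adjusted p = 0.000429). YAP1 had 55.5 CPM (log2 fold change -1.20, SE 0.212, adjusted p = 0.0356). In clone 2, 628 genes were called, 272 higher and 356 lower, and this count was 175 without wild-type replicate 1, 208 without wild-type replicate 2, 3144 without clone 6 replicate 1 and 3510 without clone 6 replicate 2. Both clones shared 615 calls in the same direction, which is 97.9% of the clone 2 calls, and 0 in opposite directions. Unchanged clones simulated against the same wild-type libraries shared 0.2 calls on average, and independent lists of these sizes would share 28.7. Across 11214 genes, which are not independent replicates, the log2 fold changes had a covariance of 0.449 against 0.0313 in the simulations, and a Pearson correlation of 0.921 against 0.402. The simulations drew every library independently, so these chance values leave out the near-identity of the clone 2 and clone 6 replicate 1 libraries. With 1 wild-type library for each clone, chosen after the data were seen, the covariance of log2 CPM differences was 0.392 or 0.382, against 0.400 with both libraries shared. The clone 2 library and clone 6 replicate 1 had a coefficient of variation of 2.68%, so part of the shared calls may come from libraries that are not independent, and with clone 6 replicate 2 alone and separate controls the covariance was 0.377 or 0.353. The shared count was 169 without wild-type replicate 1, 206 without wild-type replicate 2, 2235 without clone 6 replicate 1 and 2892 without clone 6 replicate 2.

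Clone 2 and clone 6 were compared with each other, but this comparison could hardly show whether the edited clones differ. The clone 2 library was nearly identical to clone 6 replicate 1 (coefficient of variation 2.68%). A difference between the clones therefore came mostly from that between the clone 6 replicates, which also set the spread. A lack of calls per gene thus does not show that the clones are alike. TNC, SLC6A5 and YAP1 had log2 differences, clone 2 minus clone 6, of 0.09 (SE 0.335), -0.06 (SE 0.261) and -0.21 (SE 0.204). No gene was called by edgeR at an adjusted p below 0.05, with 114 genes at an unadjusted p below 0.05, 2 genes called by DESeq2 and 0 by limma-voom. With either clone 6 library left out, 1 library was set against 1 library with the spread of the wild-type pair alone, so those counts, 872 without clone 6 replicate 1 and 5 without clone 6 replicate 2, compare libraries and not clones.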

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

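The left-out-library tests of these lists were chosen only after the list differences between clones had been seen. The comparison of clone 2 with clone 6 called 6 gene lists by camera, and each is given because the difference between the clones was itself tested. ATF4 and unfolded protein response genes were lower in clone 2 than in clone 6 (median log2 difference -1.29, adjusted p = 6.27e-06), as were inflammatory genes (-0.63, adjusted p = 0.00108). G2/M genes (0.18, adjusted p = 0.00108), cholesterol synthesis genes (0.20, adjusted p = 0.00755), histones (0.28, adjusted p = 0.00297) and epithelial markers (0.30, adjusted p = 0.0394) were higher in clone 2. With an estimated correlation the adjusted p of all 6 lists was 0.933. With 1 clone 6 library left out, 1 library was set against 1 library with the spread of the wild-type pair alone. Without clone 6 replicate 2 the calls ended, with adjusted p-values of 0.995 for the ATF4 list, 0.996 for inflammatory genes, 0.658 for G2/M genes, 0.995 for cholesterol synthesis, 0.855 for histones and 0.658 for epithelial markers. Without clone 6 replicate 1 the epithelial list also lost its call (adjusted p = 0.163). The other lists kept their calls in that setting, so those differences rested on clone 6 replicate 2. Against wild type, the ATF4 list had medians of -0.05 in clone 2, -0.14 in clone 6 replicate 1 and 1.71 in clone 6 replicate 2.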

How the results depend on the processing

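The summed libraries and the ribosomal RNA covariate were alternatives chosen after the data were seen. The 2822 genotype calls became 4274 with no low-count filter, 1821 with a fit of 3 groups, 402 when tested against a 2-fold change, 1528 with the clone 2 and clone 6 replicate 1 libraries summed and 1162 with the ribosomal RNA covariate. Other scalings, a filter of 1 CPM, DESeq2, limma-voom and leaving out ribosomal RNA genes gave 2777 to 3213. With no filter, clone 6 had 3144 calls, clone 2 had 1878, their shared calls were 1637 and the clones differed in 99 genes, against 2 with DESeq2. Leaving out 1 library gave 500 to 5971 genotype calls, 329 to 5119 for clone 6, 175 to 3510 for clone 2, 169 to 2892 shared and 0 to 872 between clones, where the highest count set 1 library against 1 library with the spread of the wild-type pair alone. The lowest of these counts against wild type came without wild-type replicate 1. List calls were 15, but 0 with an estimated correlation and 9 to 17 with 1 library left out. Cholesterol synthesis also lost its call with the replicate block (adjusted p = 0.0573) and the summed libraries (0.113), and the NADPH and glutamate lists with the ribosomal RNA covariate (0.0821 and 0.0916). The labels do not say whether replicate numbers pair the samples. R1 minus R2 correlated between wild type and clone 6 at 0.255 (Pearson) across 9950 genes. A replicate block gave 4499 genotype calls, 2569 for clone 6, 1115 for clone 2 and 1089 shared, and 0 between clones. Of 2512 values of 158 named genes under these alternatives, 2139 stayed on their side of the threshold, 363 were no longer past it, 10 newly passed it and 0 reversed. Those no longer past it were 80 without wild-type replicate 1, 73 without wild-type replicate 2, 38 without clone 2, 36 without clone 6 replicate 1, 53 with the ribosomal RNA covariate, 40 with the summed libraries and 30 with a fit of 3 groups. Apart from the settings that leave out samples or genes, the cause was not tested. Reversals were counted only where a gene was past the threshold in the main or the alternative fit. NOTCH3, past it in neither, changed sign without wild-type replicate 1. With 13572114 to 21881726 reads per library, 3 reads, the floor used for genes at 0, are 0.1385 to 0.2295 CPM on the scaled library sizes, which limits folds of genes at or near 0.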

Other observations

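All tests of explanations here were chosen only after the results they bear on had been seen. The library labelled clone 6 replicate 2 stood apart in stress genes, which are described here after their values were seen. The endoplasmic reticulum chaperone HSPA5 had 3220 CPM there, against 439 and 482 CPM in wild-type replicates 1 and 2, 330 CPM in clone 2 and 305 CPM in clone 6 replicate 1. The stress transcription factor DDIT3 had 160 CPM there and 5.17 to 8.41 CPM in the other libraries. HERPUD1, a factor of protein degradation at the endoplasmic reticulum, had 465 CPM there and 36.6 to 42.8 CPM elsewhere, and TRIB3 had 414 CPM against 48.0 to 60.3 CPM. The cytokine IL6 had 66.5 CPM there, 34.3 and 58.1 CPM in wild type, and 4.45 and 4.51 CPM in clone 2 and clone 6 replicate 1. Hypoxia targets stood apart in wild-type replicate 1, where NDRG1 had 96.2 CPM against 9.51 CPM in replicate 2, and CA9 had 26.8 against 0.934 CPM.

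The clone 2 library and the library labelled clone 6 replicate 1 were nearly identical, with 5 genes 2-fold apart, against 57 for the wild-type replicates and 443 for the clone 6 replicates. Their ribosomal RNA shares differed by a ratio of 23.5, which argues against 1 library deposited under 2 names. The coefficient of variation of 2.68%, below that of both replicate pairs, is consistent with the same RNA or culture behind both libraries, a hypothesis. Separate cultures of the clones grown side by side cannot be told apart from this, since the labels give no batches and the only yardstick is the 9.64% of the wild-type pair. Under the first reading the edited group would hold fewer independent samples, and the summed alternative gave 1528 genotype calls.

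Expression was lower along the long arm of chromosome 11 (median log2 fold change -0.47, 182 of 361 genes called lower and 3 higher) and along chromosome 13 (-0.43 over 174 genes), while the wild-type replicates differed on the chromosome 11 arm by a median of -0.01. GC content was argued against, since the median shift against other genes of similar GC content was -0.33 or lower in each of 4 GC bins of both segments. All 10 blocks of at least 50 consecutive genes (100%) had medians below -0.2, and a change in copy number of the segments is a candidate explanation that was not tested on DNA. YAP1 fell by 0.59 more on the log2 scale than its arm, written -0.59 with an SE of 0.14, which argues against the segment shift as the whole cause, although 6.4% of the genes on the arm were as low. Smaller upward shifts were seen on the short arms of chromosomes 1 and 7 and the long arm of chromosome 8 (medians 0.31, 0.33 and 0.33), and on 21q and 5q (0.21 and 0.18). Smaller downward shifts were seen on 9p, 15q and 2q (-0.25, -0.22 and -0.20) and on 1q and 5p (-0.19 each).

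Transcripts such as EPB41L3 and TNC fell nearly completely, and fibroblasts lost from the wild-type line would have brought their abundant transcripts to it, but DCN had 0 reads in both wild-type libraries, LUM 1 read in replicate 1 and 0 in replicate 2, and COL1A2 6 reads in each. The highest mean of these 3 was 0.24% of the fall of COL3A1 in CPM, which argues against fibroblasts although FAP fell (log2 fold change -2.72). COL3A1 fell as well, but it lost its call without wild-type replicate 1. Loss of pericytes stays open, since PDGFRB went from 63.1 and 52.3 CPM in wild type to 29.8, 30.1 and 13.2 CPM and ABCC9 and KCNJ8 fell, while RGS5 rose by 3.06 on the log2 scale (adjusted p = 0.0807 without wild-type replicate 1 and 0.0782 without wild-type replicate 2). Of 84 genes at least 8-fold lower in clone 2 than in both wild-type libraries, 63 (75%) were also 8-fold lower in clone 6 replicate 2, but independent drift in each clone cannot be told apart from shared changes while the clone 2 and clone 6 replicate 1 libraries may be of the same culture. Whether the 62 genes at least 8-fold lower in all 3 edited libraries follow the IDH1 edit or a parent cell shared by the clones cannot be told apart either, because further unedited clones were not analysed here.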
